A study of Caenorhabditis elegans with 4 samples.

How the data were processed

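Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on formaldehyde-fixed mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, with a rabbit polyclonal antibody against SWD-3. Per the labels' protocols, chromatin was sheared by sonication, part of each extract was kept as input DNA, and libraries were sequenced on Illumina instruments. The labels name 4 samples, 2 ChIP libraries and 2 input libraries, numbered 1 and 2 in each kind. The labels do not say whether the replicates came from separate embryo preparations. The p-values given here measure spread over peaks, bins or chromosomes of these libraries, which may be technical.

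The measurements used here were 3 peak lists, all in coordinates of WormBase WS220 per the file headers; the submitters' processing notes name BWA and the build ce10. One list was deposited for each ChIP replicate, and its source column names MACS with no version. The third list was deposited for the whole series, and its source column names MACS v2. The peak-calling thresholds, the control used, and whether the libraries were pooled or merged for the series list are not given in the sources used here. Each peak carries a start, an end and 1 deposited score, the authors' own value per peak. No header names the scale of the score. In the replicate lists the smallest scores were 50.03 and 50.01, and 3100 recurred in 3 and 8 peaks. In the series list the smallest score was 1.3. Scores were therefore used to rank peaks and to compare medians within a list, and between lists only through correlations over overlapping peaks, of ranks and of log10 scores. No score was set against another list's as larger or smaller. Read values of the input libraries were not analysed here.

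Everything else was computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks were called shared when they overlapped by at least 1 bp. The overlap expected by chance came from 10000 circular rotations, in which all peaks of 1 list were moved together along each nuclear chromosome, which keeps their widths and spacing; the test was one-sided for an excess, and 0.0001 is the smallest p it can give. Peak midpoints were counted in 1 Mb bins and X was compared with the autosomes by a two-sided permutation of bins with 100000 draws. Neighbouring bins are not independent, so those p-values are likely to be too small. Chromosome centres were the middle 50% of each chromosome and arms the outer 25% on either side, and the log2 ratio of their peak densities was tested over the 6 nuclear chromosomes by an exact two-sided sign-flip permutation test, whose smallest p is 0.031. Chromosome lengths were taken as the largest coordinate of any peak, which gave 100.2 Mb in all. Correlations of scores were taken across overlapping peaks, which are not independent replicates, with 100000 permutations and a smallest p of 1e-05. Shares of peaks have 95% Wilson intervals, which cover counting error only. Benjamini-Hochberg adjustment was applied within each family of tests: 6 overlaps, 6 correlations of scores, 10 tests of centres against arms and 13 of X against autosomes. The families of centre and X tests include the planned lists and the subsets added after the data were seen.

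The lists hold no read counts, so the sequencing depth of the libraries is unknown and the precision of a single peak cannot be given. The procedures were tested on simulated data. With 300 peaks planted in common between randomly placed lists of the replicates' sizes, 273 more overlaps were found than in rotations; with an X density planted at 0.5 of the autosomal one, the median ratio recovered was 0.481; and when arm peaks were thinned to give a planted log2 ratio of 1, the ratio recovered was 1.05. Among 200 simulations with no difference between X and autosomes, 4% had p at or below 0.05, and among 40 with randomly placed lists, 0% did. The simulated bins were drawn independently of their neighbours and the lists were placed evenly along the chromosomes, unlike the real ones. These shares therefore do not give the error rates of the tests on the deposited lists.

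The comparisons, gene lists and alternatives were fixed before the data were examined. The alternatives were a 50% reciprocal overlap, midpoints within 200 bp, the higher-scoring part of each list, lists of equal length, random placement in place of rotation, each replicate list alone, peaks found in both replicates, 500 kb bins and another definition of centres. Comparisons with gene 5' ends, gene lists, non-coding genes, operon-like genes, base composition and the antigen sequence had been planned and were not made. The gene table at hand is of assembly WBcel235, whose coordinates differ from those of WS220, and no genome sequence was used here. By the rule set for that case, the 10 highest-scoring series peaks are named by position. Other regions named in the text were chosen after their values were seen. The comparisons by peak width, of chromosome ends, of the difference between lists in centres and arms, and of sharing on X were likewise added after the data were seen.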

Results

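SWD-3 is a WD40-repeat protein of the WDR5 family, a component of the complexes that methylate lysine 4 of histone H3. Its binding sites were mapped by ChIP-seq in wild-type C. elegans embryos of mixed stages, in 2 ChIP libraries each with an input DNA library. The results rest on 3 deposited peak lists in WS220 coordinates. Without input values, SWD-3 binding could not be told apart from regions that give peaks whatever the antibody. Replicate 1 held 2698 peaks with a median width of 420 bp, covering 1.42 Mb. Replicate 2 held 4580 peaks with a median width of 538 bp, covering 2.81 Mb. The list of the whole series held 9630 peaks with a median width of 319 bp, covering 6.89 Mb or 6.87% of the nuclear chromosomes. Read depth is unknown for all lists, so a missing peak means only that none was called.

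The first question was which peaks were found in both ChIP libraries. Of the replicate 1 peaks, 1685 overlapped a replicate 2 peak (62.5%, 95% Wilson interval 60.6 to 64.3). Rotated lists gave a mean of 139 such peaks and at most 411, so the overlap was 12.1 times that expected (p = 0.0001, one-sided rotation permutation test, the smallest it can give; Benjamini-Hochberg adjusted over 6 overlaps, also 0.0001). In the other direction, 1600 of the replicate 2 peaks (34.9%, interval 33.6 to 36.3) overlapped a replicate 1 peak. The excess shows that calls recurred at the same places. Regions that give peaks whatever the antibody would recur too, and they were not separated here. Sharing rose with peak score in both lists. In the highest-scoring decile, 87% of replicate 1 peaks and 82.8% of replicate 2 peaks were found in the other replicate, against 43.3% and 15.1% in the lowest decile. Peaks were also wider there, with median widths of 804.5 and 814 bp in the highest decile against 201 and 310 bp in the lowest. Wide peaks meet a 1 bp overlap more easily, and score was not separated from width in this comparison. Across the 1690 overlapping pairs of peaks, which are not independent replicates, the scores were correlated (Spearman's rho = 0.45, Pearson's r of log10 scores = 0.45, permutation p = 1e-05 for each, the smallest possible; adjusted over 6 tests 1.2e-05).

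**Figure D1:**
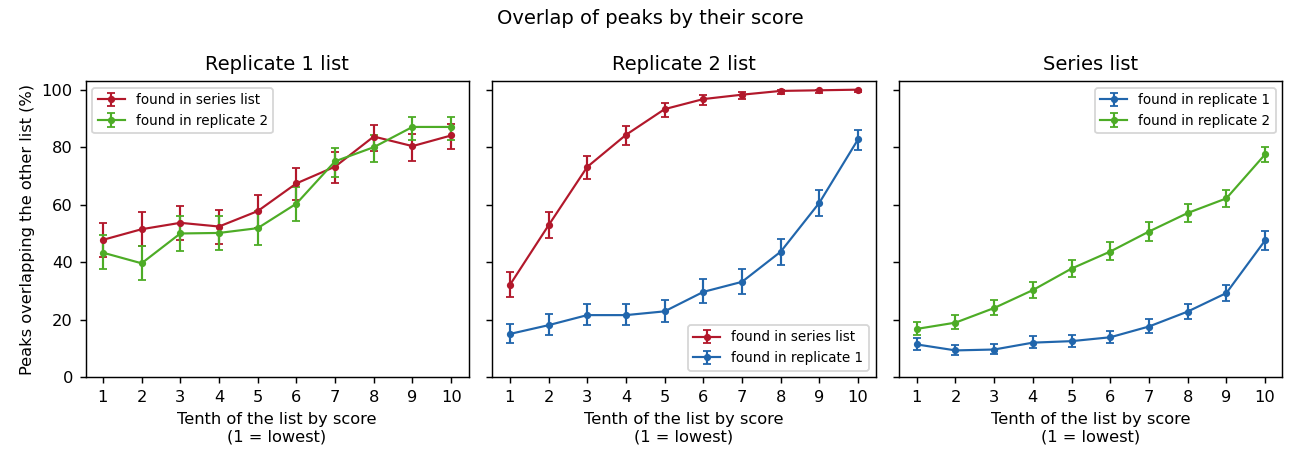
Percent of peaks in each list (panels) that overlap a peak of another list (colours), by decile of the authors' score from lowest (1) to highest (10); bars are 95% Wilson intervals. For replicate 2, overlap with the series list rose from 32.1% to 100% and overlap with replicate 1 from 15.1% to 82.8%.

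The 10 highest-scoring peaks of the series list all overlapped a peak in both replicates, and they lay on chromosomes I, II, IV and V. The first was at chromosome I 1958285 to 1958836, with a series score of 171.36; it overlapped the replicate 2 peak of rank 18 of 4580 and the replicate 1 peak of rank 203 of 2698. The second was at chromosome II 255023 to 255603 (score 161.17, replicate 2 rank 17, replicate 1 rank 39), and the third at chromosome IV 1659005 to 1659504 (score 159.26, ranks 25 and 61). Chromosome I also held the peaks at 6723045 to 6723877 (score 158.31) and 14737222 to 14737714 (score 156.16). The former ranked 1034 of 2698 in replicate 1, where its score of 139.83 lay above the list's median of 103.41, and 30 of 4580 in replicate 2. Chromosome V had 1 peak in the group, at 14038307 to 14039027 (score 157.40), which carried the recurring score of 3100 in replicate 2 and ranked 189 in replicate 1. The remaining peaks formed 2 close groups on chromosome II. One pair lay at 10033357 to 10034162 and 10034511 to 10035102 (scores 156.54 and 150.15). The other lay at 5346335 to 5347616 and 5347670 to 5350678 (scores 149.21 and 153.88), and the latter of these was 3009 bp wide. All 10 peaks ranked between 6 and 36 in replicate 2, and between 39 and 1034 in replicate 1.

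Several of the strongest peaks of the replicates lay elsewhere and scored low in the series list. Others scored high there, such as the replicate 2 peaks of rank 2, 3 and 5 (highest series scores 113.38, 85.58 and 94.6). The regions described next were picked after their values were seen. At the right end of chromosome I, the part of the genome that carries the array of large ribosomal RNA genes, a peak from 15060252 to 15071351 in replicate 1 and from 15060188 to 15071363 in replicate 2 had a score of 3100 in each. The series list had 2 peaks overlapping it, 10456 bp wide together, whose highest score was 2.3. On the right arm of chromosome V, the region at 17119902 to 17127840 was the first-ranked peak of replicate 1 (3163.8) and had 3100 in replicate 2, while the highest series score there was 4.61. A replicate 1 peak at chromosome V 3434572 to 3441153 (rank 6) overlapped a replicate 2 peak with a score of only 52.37 and no series peak. The left tips of the chromosomes, where telomeric repeats lie, also differed between the lists. A peak starting at base 1 was called on 6 of 6 chromosomes in replicate 1, on 5 of 6 in replicate 2 (none on III) and on 0 of 6 in the series list. In replicate 1 these tip peaks scored from 196.66 on IV (rank 704 of 2698) to 771.56 on I (rank 113). In replicate 2 they all scored below the list's median of 221.94, from 53.88 on IV (rank 4480 of 4580) to 215.11 on I (rank 2335), near that median. The mitochondrial genome had no peak in either replicate and 2 low-ranked peaks in the series list, at 12062 to 12492 and 12578 to 12730.

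The next comparison was of the series list with the replicates, since the way it was made is not stated. It contained 83% of the replicate 2 peaks (interval 81.9 to 84.1) and 65.2% of the replicate 1 peaks (63.4 to 67.0), 7.43 and 6.28 times the overlap of rotated lists (p = 0.0001 for each, rotation permutation test). The series list may rest on the same reads as the replicate lists. An excess would then follow from that alone, so it is no independent support for the sites. All 458 peaks in the highest-scoring decile of replicate 2 had a series peak, whereas 43 of the 269 highest-scoring peaks of replicate 1 had none. Scores of overlapping peaks were more closely correlated between the series list and replicate 2 (rho = 0.62, 4056 pairs) than between it and replicate 1 (rho = 0.10, permutation p = 5e-05, 1890 pairs; Pearson's r of log10 scores 0.03, permutation p = 0.203); the difference between these correlations was not tested. The weak correlation with replicate 1 depended on the overlap required: at a 50% reciprocal overlap it was rho = 0.40 and r = 0.38 (1039 pairs, permutation p = 1e-05 for each), and that with replicate 2 was rho = 0.82 (2509 pairs).

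Most of the series list had no counterpart in the replicates. Only 1467 series peaks (15.2%, interval 14.5 to 16) overlapped a peak in both replicates, 2570 (26.7%) in replicate 2 alone and 327 (3.40%) in replicate 1 alone, while 5266 (54.7%, interval 53.7 to 55.7) overlapped none. High-scoring narrow peaks were the exception. In the top 25% of the list by score, 1566 of 1685 peaks of up to 1000 bp (92.9%, interval 91.6 to 94.1) overlapped a peak in at least 1 replicate, against 148 of 739 wider ones (20.0%, interval 17.3 to 23.1). Peaks found in both replicates had a median score of 17.67 against 7.34 for all others, a difference of 10.33 (two-sided permutation test, p = 1e-05, the smallest possible). This difference too may reflect reads shared between the lists. The share without a replicate peak did not change steadily with width. It was 62.3% for series peaks of up to 200 bp, 40.3% (38.9 to 41.9) for those wider than 200 and up to 400 bp, and 56.1% up to 800 bp. It was 79.8% both for those wider than 800 and up to 1500 bp and for the 894 wider than 1500 bp (77.0 to 82.3). Peaks wider than 1500 bp made up 9.28% of the list and 51.3% of its covered length, against 2.56% of the peaks and 16.2% of the length in replicate 1, and 2.21% and 11% in replicate 2. Of the 10 widest, 9 lay on the right arm of chromosome V. The widest ran from 17044395 to 17067930 on V (23536 bp, score 44.81) and the next from 19435457 to 19458752 (23296 bp, score 42.15), and neither overlapped a replicate peak. The exception was on the left arm of chromosome IV, at 890242 to 912597.

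**Figure D2:**
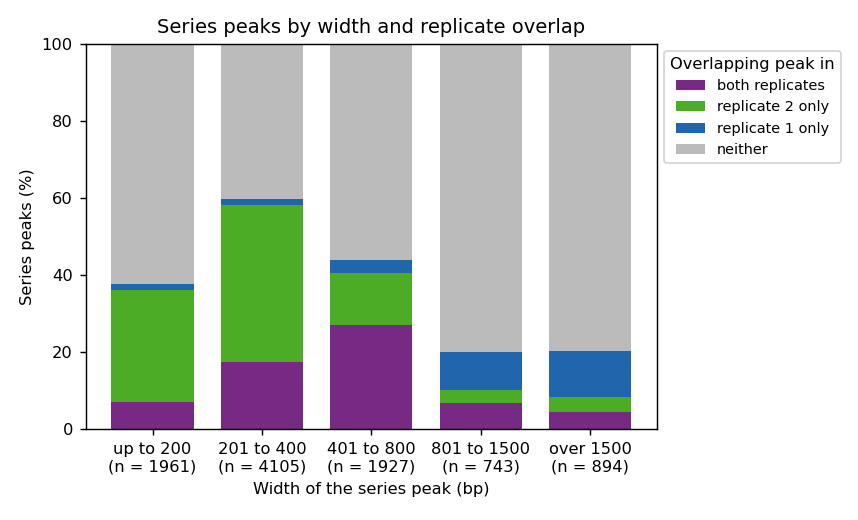
Percent of series peaks in each width class (bp) that overlap a peak in both replicates, in 1 replicate only or in neither; n is the number of series peaks. The share without a replicate peak was 62.3% up to 200 bp, 40.3% for peaks wider than 200 and up to 400 bp, and 79.8% above 1500 bp.

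Along the chromosomes, the lists differed in where peaks were dense. In the series list the arms held 2.25 times as many peaks per Mb as the centres, the mean log2 ratio of centre to arm being -1.17 ± 0.36 (SD, n = 6 chromosomes), with arms higher on 6 of 6 chromosomes (exact sign-flip permutation test, p = 0.031, the smallest possible; adjusted over 10 lists and subsets 0.0781). The right arm of I had 254 peaks per Mb against 81.3 in its centre, the left arm of II 204 against 50.3, the left arm of III 191 against 71.8 and the right arm of V 204 against 49.3. The densest 1 Mb bins were chromosome I 12000001 to 13000000 with 318 peaks and chromosome II 1000001 to 2000000 with 304. In chromosome V 17000001 to 18000000, series peaks covered 664 kb, and the replicate peaks 24.8 and 28.6 kb.

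Neither replicate list as a whole showed this arm excess. The mean log2 ratio of centre to arm was 0.17 ± 0.31 in replicate 1 (centres higher on 3 of 6 chromosomes, exact p = 0.25) and 0.44 ± 0.29 in replicate 2 (5 of 6 chromosomes, exact p = 0.0625, X being the exception), both SD over n = 6 chromosomes. The log2 ratio was lower in the series list than in either replicate on 6 of 6 chromosomes. The mean difference was -1.61 ± 0.59 from replicate 2 and -1.34 ± 0.51 from replicate 1 (SD, n = 6 chromosomes, exact p = 0.031 for each, the smallest possible). Peaks found in both replicates were denser in centres on every autosome and nearly even on X. The log2 ratio was 0.52 ± 0.37 counted on replicate 1 and 0.50 ± 0.35 counted on replicate 2 (exact p = 0.031 for each, adjusted 0.0781). X lay just above even in these counts, at 0.05 and 0.02. Counted on the series list, the ratio was 0.38 ± 0.31, with X at -0.06 (exact p = 0.094, adjusted 0.117). Replicate 1 peaks not found in replicate 2 leaned the other way, with a log2 ratio of -0.35 ± 0.38 and arms denser on 5 of 6 chromosomes (exact p = 0.094; adjusted 0.117), whereas replicate 2 peaks not found in replicate 1 had 0.41 ± 0.30 (exact p = 0.0625). Of the series peaks found in replicate 1 only, 68.2% (63 to 73) lay in arms. These were wide, with a median of 907 bp against 369 bp for those found in both replicates. Of them, 32.4% were wider than 1500 bp, a width at which 91.1% of all series peaks lay in arms. Wide peaks also meet a 1 bp overlap more easily, so this share was not separated from width. Among series peaks that overlapped no replicate peak, 88.5% (87.6 to 89.3) lay in arms, compared with 43.8% (41.2 to 46.3) of those found in both replicates.

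**Figure D3:**
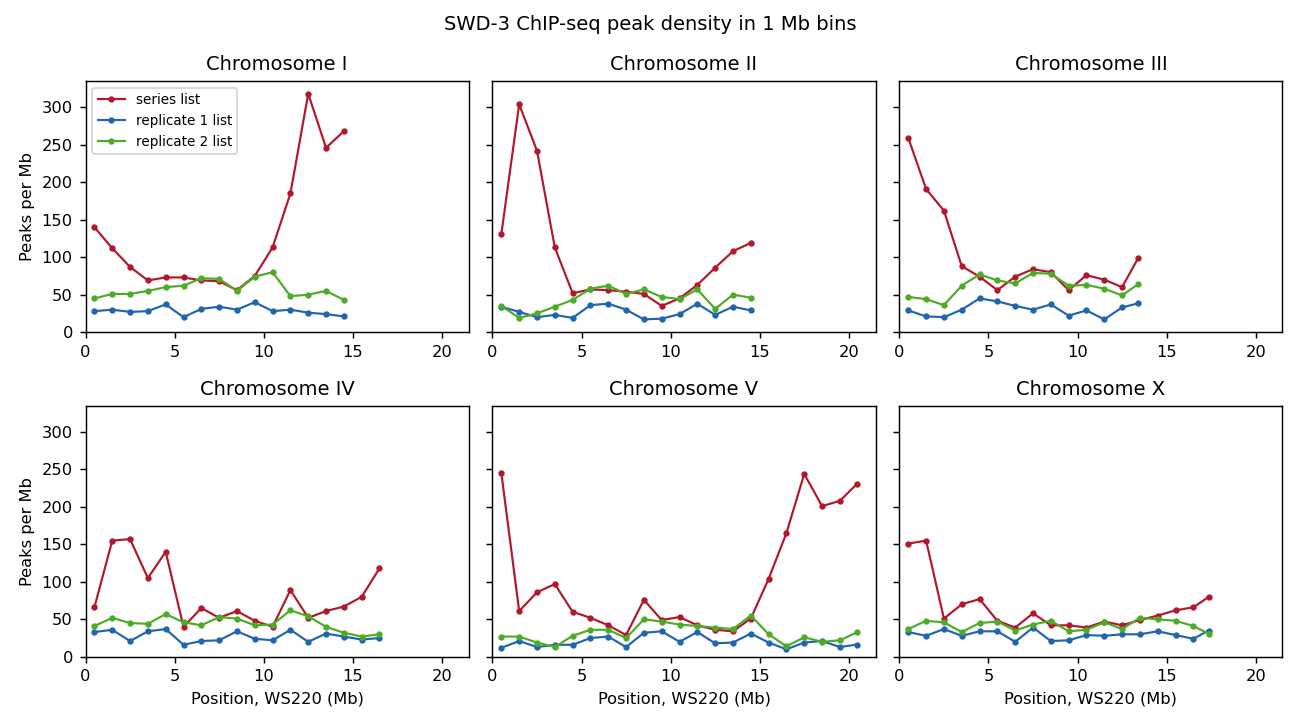
Peaks per Mb in 1 Mb bins along the 6 nuclear chromosomes (WS220 position in Mb) in the series list and the replicate lists. The series list rises to 318 peaks per Mb on the right arm of I and 304 on the left arm of II, where the replicate lists hold 19 to 50.

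The X chromosome was compared with the autosomes because the hermaphrodite X is dosage compensated in worm embryos. In the series list X had 65.2 ± 34.3 peaks per Mb (SD, n = 18 bins of 1 Mb) and the autosomes 103.2 ± 69.4 (n = 82 bins), a ratio of 0.632 (two-sided permutation test over bins, p = 0.0248; adjusted over 13 tests 0.0645). In replicate 2 the ratio was 0.904 (42 ± 6.62 against 46.5 ± 15.7, permutation p = 0.242). In replicate 1 it was 1.13 (29.7 ± 5.46 against 26.4 ± 7.85, permutation p = 0.0858), so over whole chromosomes neither replicate differed beyond the spread between bins. In chromosome centres alone, replicate 2 had fewer peaks on X than on the autosomes together. X had 41.4 ± 4.67 per Mb (n = 9 bins) against 54.9 ± 13.6 (n = 42 bins, ratio 0.755, permutation p = 0.0056, adjusted 0.0364). X was not the lowest chromosome, as the centre of V held 40.8 per Mb. The centres of the other autosomes held 50.9 to 71.4. The ratio in centres was 1.01 in replicate 1 (permutation p = 0.951) and 0.736 in the series list (permutation p = 0.0796). Replicate 2 peaks that were shared with replicate 1 were denser on X than on the autosomes together, with 19.5 ± 4.90 per Mb against 15.2 ± 6.67 (ratio 1.28, permutation p = 0.0109, adjusted 0.0472). Those not shared were sparser on X, with 22.5 ± 4.64 against 31.3 ± 10.9 (ratio 0.720, permutation p = 0.0013, adjusted 0.0169). X was not the extreme chromosome in either case. Over its whole length, III held more shared peaks per Mb than X (281 in 13.783 Mb against 348 in 17.713 Mb). V held fewer peaks per Mb that were not shared. It had 213 shared of 665 peaks in 20.92 Mb, and X 348 of 748. Counted on replicate 1, the ratio of X to autosomes was 1.25 for shared peaks (permutation p = 0.0244), which did not pass after adjustment (0.0645). Peaks not shared showed no detectable difference between X and autosomes (0.930, permutation p = 0.552).

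Sharing between the replicates was accordingly higher on X. Of 748 X-linked replicate 2 peaks, 46.5% (43.0 to 50.1) were found in replicate 1, against 32.7% (31.2 to 34.2) of 3832 autosomal ones; the 5 autosomes ranged from 30.4% on I to 34.6% on II. Over 1 Mb bins the mean difference was 13.9 percentage points (18 X bins and 85 autosomal bins with at least 5 peaks, permutation p = 1e-05, the smallest possible). In the other direction, 68.6% (64.5 to 72.4) of X-linked replicate 1 peaks were found in replicate 2 against 61.0% (58.9 to 63) of autosomal ones, a difference over bins of 8.78 percentage points (permutation p = 0.0404). Chromosome III exceeded X in this direction, at 72.6%.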

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

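The joined and covered-bp counts, the subsets in either or no replicate, the centres alone and a repeat without the 100 widest peaks (60.6% shared) were chosen after seeing the data. The overlap between the replicates exceeded that of rotated lists under 5 alternatives and that of randomly placed peaks (12.2 times) under another, with 39.7% of replicate 1 peaks shared at a 50% reciprocal overlap and 48.5% when replicate 2 was reduced to the length of replicate 1. The score correlation between the replicates rose to 0.62 at a 50% reciprocal overlap. The percent of series peaks found in both replicates moved from 15.2% to 7.24% at a 50% reciprocal overlap, which admits fewer pairs of unequal width, and to 22.5% in the higher-scoring part of the list; their score difference was 19.8 and 10.6 there, in place of 10.33, with the smallest possible p in each. The log2 ratio of centres to arms was -0.85 in the higher-scoring part of the series list, -1.03 with a shorter central region, -0.30 after joining peaks under 2000 bp apart and -2.11 counted in covered bp, each with exact p = 0.031. It reversed to between 0.17 and 0.44 in each replicate list alone (exact p = 0.25 in replicate 1 and 0.0625 in replicate 2). In series peaks found in both replicates it reversed to 0.38 (exact p = 0.094). The ratio of X to autosomes was 0.585 and 0.629 in the higher-scoring part and with 500 kb bins. It lay between 0.904 and 1.13 in each replicate list alone, reversing in replicate 1. It also reversed to 1.24 in series peaks found in both replicates (permutation p = 0.0386, adjusted 0.0836). The ratio of the whole series list passed the threshold only before adjustment (permutation p = 0.0248, adjusted 0.0645). Even before adjustment, the ratio did not pass in series peaks found in either replicate (0.892), in none (0.435) or in chromosome centres (0.736), the latter with fewer bins. The cause of the other changes was not tested. No paired analysis was possible because only the ChIP libraries had peak lists and no values of the input libraries were used here. Peaks per protein-coding gene and the alternatives for genes and base composition were not run. Without read counts, the effect of depth on the length of the lists cannot be assessed.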

Other observations

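The tests of low-scoring calls, of pairing-centre arms and of series peaks found in either replicate were chosen after the results were seen. Each worm chromosome has a meiotic pairing centre near one end, the right end of I and V and the left end of II, III, IV and X. In the series list, peaks were denser in the arm with the pairing centre on 6 of 6 chromosomes, from 1.67 times on IV to 2.58 times on III. Among series peaks without a replicate peak, the ratio ranged from 1.91 on IV, with 87.8 peaks per Mb in the left arm and 45.96 in the right, and 2.09 on V to 6.38 on III, with 141 in the left arm and 22.1 in the right. Replicate 1 and replicate 2 showed this on 2 of 6 chromosomes each, with mean ratios of 0.934 and 0.906.

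The arm excess of the series list was weighed against 3 technical accounts. A looser threshold on the same libraries would make the weakest replicate peaks lean to the arms. In the lowest-scoring decile, 40.4% (36 to 44.9) of replicate 2 peaks and 48.1% (42.3 to 54.1) of replicate 1 peaks lay in arms. The share was 53.7% (47.7 to 59.6) in the next decile of replicate 1, and 88.5% among the unsupported series peaks. The replicate lists hold no peak scoring below 50.01, so where weaker ones lie is unknown and a looser threshold cannot be excluded. Low-scoring calls are not the whole account, because in the higher-scoring part of the series list the log2 ratio of centre to arm was still -0.85 with arms higher on 6 of 6 chromosomes, although the share in arms was lower in the highest-scoring decile (59.5%) than in the lowest (78.4%). Splitting of wide domains into many calls does not remove it either, since joining peaks under 2000 bp apart left the log2 ratio at -0.30 with arms higher on 6 of 6 chromosomes, although smaller than the -1.17 before joining. As a hypothesis, the unsupported peaks may follow a chromosomal feature of the pairing-centre arms; their density there (mean ratio between arms 3.31, 6 of 6 chromosomes, exact sign-flip p = 0.031, the smallest possible) restates the observation that prompted it, no independent test was made, and a control that differed between the calls, another peak-calling mode for wide regions or added libraries stay open, as no values for them were at hand.

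The low X share of the series list (0.632, against 0.904 in replicate 2) did not pass after adjustment (adjusted permutation p = 0.0645). It may follow in part from the same arm excess. With the arms left out, the ratio of the series list was 0.736, near the 0.755 of replicate 2, which was the outcome set beforehand for this account. That outcome cannot decide it, because replicate 2 itself fell from 0.904 to 0.755 without an arm excess. In replicate 1 the ratio in centres was 1.01. A ratio below 1 remained in centres, past the threshold in replicate 2 (permutation p = 0.0056, adjusted 0.0364) and not in the series list (permutation p = 0.0796). The arm excess does not account for that part. In replicate 2 it was not particular to X, since the centre of V held 40.8 peaks per Mb and that of X 41.4. For series peaks found in either replicate the ratio was 0.892, between the bounds set for and against an account by unsupported peaks alone, so that account cannot be told apart from others with these lists. No biological explanation was tested.

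The higher sharing of X peaks remained when replicate 2 peaks were grouped by strength or by width, each taken alone. The 2 were not held alike together. Median scores were 219 on X and 223 on autosomes, and within deciles of score X peaks were found in replicate 1 more often in 10 of 10 deciles, by 15.1 percentage points on average. Peaks on X were somewhat wider, with a median of 560 bp against 534 bp on autosomes. Within 5 groups by width the excess was 11.1 ± 9.02 points (SD) and positive in 5 of 5 (exact sign-flip p = 0.0625, the smallest possible). More ready calling of X-linked sites in replicate 1 than in replicate 2 stays open as a part of the account. The ratios of X to autosomes were 1.13 and 0.904 over whole chromosomes and 1.01 and 0.755 in centres. The difference between these ratios was not tested. Such calling alone does not cover the other direction. There 68.6% of X-linked replicate 1 peaks were found in replicate 2, against 61.0% of autosomal ones (8.78 percentage points over bins, permutation p = 0.0404). Chromosome III exceeded X in that direction, at 72.6%. No biological explanation was tested.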
